A study of Drosophila melanogaster with 8 samples.

How the data were processed

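The data were 8 RNA sequencing libraries of whole Drosophila melanogaster embryos, 2 for each of 4 groups. Per the labels' protocols, total RNA came from 50 mg collections of frozen embryos of stages 8 to 16 and was sequenced as single reads of 50 bp, with 1 lane for each of the 2 experiments. The labels call the replicates biological. Experiment and lane cannot be told apart, so each misexpression group was tested against the control of its own experiment.

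The authors deposited 1 table for each experiment, with 17321 genes by symbol. Per the file headers, the authors gave total RPKM (reads scaled to transcript length and library size) for each gene and library on a linear scale. Per the file headers, further deposited columns hold the log2 of those RPKM values. The aligner, counting tool, genome build, annotation and use of strand are not given in the sources used here, so no coordinates are printed. How reads of overlapping or near-identical genes were assigned is not given either. The lowest value is a floor, 0.002 RPKM in the first table and 0.003 RPKM in the second. The deposited raw count columns were proportional to RPKM, within 1% or rounding, for 4512 genes in both tables, and held part of the reads, often none, for others. Of 7660 genes with at least 10 RPKM in a library of the first table, 2791 had a count of 0 in every library, as had 2739 of 7462 in the second. For 414 genes a dash replaced the count. The planned tests on raw counts therefore were not made. A limma test on RPKM, named as the fallback before the data were examined, gave all main results. The fold changes that the authors deposited compare single libraries and equal the ratios of the RPKM columns within 0.01 on the log2 scale, where both libraries exceed 1 RPKM. Of the 17321 symbols, 12677 are current in the reference gene names and 16328 match a current or older symbol. Square brackets in symbols were read as round ones, and 4 list members were matched by hand to a spelling in the files.

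RPKM values were used as log2(RPKM + 1). Genes with at least 1 RPKM in at least 2 libraries of a fit were tested with limma's trended moderated test, and p-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. Quad was compared with Ctrl and QuadD with Ctrl-D in fits of 4 libraries each. The difference of both effects and the comparison of Ctrl with Ctrl-D came from a fit of all 8 libraries with 4 groups. Confidence intervals are 95%. The 24 gene lists, with 609 members in all, were also written before the data were examined. They cover cell cycle drivers and brakes, DNA replication, mitosis, neuroblast, temporal, Hox, Notch, neuron differentiation, neuron subtype, glia, sensory organ, muscle, epidermis, trachea and salivary gland, gut, hemocyte and fat body, early patterning, maternal, apoptosis, heat shock, immune, ribosome biogenesis, and Polycomb and trithorax genes. Of their members, 2 had no symbol in the files, and some genes stand in more than 1 list. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists. The genes ase, SoxN, wor, Kr, en and w were kept out of every list. Camera with an estimated correlation and fry were alternatives. With 2 libraries per group the estimate and its test have few degrees of freedom, so a call lost there is weak evidence against a list. The preset correlation called 13 lists between Ctrl and Ctrl-D, so its p-values alone are weak evidence for an effect of the factors.

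Genes to name were fixed by a rule before the data were examined. It takes ase, SoxN, wor, Kr, en, w and da, and the cell cycle genes CycE, E2f1, stg and dap. Per comparison it adds the 6 largest rises and 6 largest falls among genes that passed, with a mean of at least 10 RPKM in the higher group (the rule was written for CPM), no overlap of the libraries and a symbol that is not only a CG or CR number. It also takes up to 4 members with the smallest p per list, and the 5 genes with the smallest p per direction of the difference of effects. The rule on CG and CR symbols holds for these 5 genes too.

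Depth was compared through the reads per RPKM unit in genes with whole counts. Relative to the deepest library, QuadD replicate 1, it was 83.1% and 87.2% in Quad, 85.6% and 82.9% in Ctrl, 42.5% in QuadD replicate 2 and 41.5% and 39.6% in Ctrl-D. Replicates of each group differed beyond sampling noise (chi-square per degree of freedom 19.5 in Quad, 18.8 in Ctrl, 5.51 in QuadD and 9.15 in Ctrl-D), more than a repeated count of the same library would; separate preparations of 1 RNA sample would also exceed this noise, so the values do not show that the samples were independent. As a check on the RPKM test, limma's voom was run on the genes with whole counts, a choice made after the data were seen. Further alternatives were other scalings, filters and pseudocounts, a fit of all 8 libraries, the replicate number as a block and leaving out each library in turn.

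The scripts were tested on simulated data in which 200 genes above a minimum level were changed. Noise was drawn for each gene alone, without shifts shared by the genes of a library. In the real data 47.5% of genes were called in Quad and 55.0% in QuadD, far more than were changed here. The rates below therefore check the scripts and do not give the power or error of the real tests. Of 2-fold changes the test found 61% for Quad against Ctrl (10330 genes), 73% for QuadD against Ctrl-D (10047 genes), 57% for the difference of effects (10498 genes) and 79% for Ctrl against Ctrl-D (10486 genes). Of 4-fold changes it found 93%, 95%, 89% and 98%, in the same order. Other genes called, leaving out the mitosis list, numbered 8, 6, 4 and 10. Computations used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.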

Results

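Gene expression was measured by RNA sequencing of whole Drosophila embryos collected across stages 8 to 16, the period in which neural stem cells (neuroblasts) form, divide and stop dividing. In the first experiment, the ubiquitous driver da-Gal4 switched on 4 transgenes for early neural transcription factors, ase, SoxN, wor and Kr (Quad, n = 2 libraries). These embryos were compared with embryos that carried the driver alone (Ctrl, n = 2). In the second experiment, the labels name the same driver with altered forms of 3 of these factors together with wild-type Kr (QuadD, n = 2). Kr RNA was not raised in those libraries over their own control. Per the labels, ase was fused to the VP16 activation domain, and SoxN and wor to the repressor domain of Engrailed (EnR). Driver-only embryos of that experiment served as control (Ctrl-D, n = 2). The deposited names of both control groups include OregonR, and those of Quad and QuadD do not. Strain background therefore cannot be told apart from the transgenes in either comparison. The study asked how proliferation is controlled as neural lineages advance, and the libraries address what these factors change when present throughout the embryo. Levels are the deposited RPKM of each gene, given as mean ± SD over the 2 libraries of a group. Fold changes are log2 values ± SE on the log2(RPKM + 1) scale, which understates the change of genes with low levels. Adjusted p-values for genes are from limma with Benjamini-Hochberg adjustment. The deposited read counts hold only part of the reads of many genes. They summed to 5660187 and 6171860 in Quad, 5908806 and 5783886 in Ctrl, 6740835 and 2922038 in QuadD, and 2893271 and 2765722 in Ctrl-D, for replicates 1 and 2.

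The misexpressed genes were examined first, since they check the labels. In Quad, ase rose from 31.2 ± 4.12 to 108.1 ± 1.54 RPKM (log2 fold change 1.77 ± 0.12, adjusted p = 0.000257). The gene wor rose from 44.2 ± 3.03 to 180.0 ± 10.7 RPKM (2.00 ± 0.10, adjusted p = 9.67e-05). Kr rose from 40.6 ± 7.73 to 102.8 ± 9.44 RPKM (1.33 ± 0.15, adjusted p = 0.00123). For these 3 genes, both Quad libraries lay above both Ctrl libraries. SoxN stood at 109.2 ± 16.1 RPKM in Quad and 84.8 ± 1.18 RPKM in Ctrl and missed the threshold (0.35 ± 0.12, adjusted p = 0.0536). It passed without Quad replicate 1 (0.50), with a filter at 5 RPKM, with all 8 libraries in the fit and with the replicate block (0.35 in each). In the libraries labelled QuadD, ase rose from 39.0 ± 0.0714 to 120.2 ± 3.16 RPKM (1.60 ± 0.08, adjusted p = 8.73e-05). There wor rose from 60.5 ± 0.188 to 259.4 ± 8.53 RPKM (2.08 ± 0.08, adjusted p = 5.38e-05). SoxN rose by 0.41 ± 0.10 (adjusted p = 0.0162), a call lost without QuadD replicate 1 (0.39) and without QuadD replicate 2 (0.43). Kr, although named among the QuadD transgenes, was at 66.1 ± 1.85 RPKM against 63.3 ± 8.29 RPKM in Ctrl-D (0.066 ± 0.11, adjusted p = 0.637). Gene totals do not separate the embryos' own transcripts from those of the transgenes.

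Genes that lend parts to the constructs or the driver were examined in the same way. The gene en, source of the repressor domain, did not pass in Quad (-0.27 ± 0.15, adjusted p = 0.191) or in QuadD (-0.14 ± 0.09, adjusted p = 0.235); without Quad replicate 2 it passed in Quad (-0.48). The driver gene da did not pass either (0.23 ± 0.10 and 0.21 ± 0.11, adjusted p = 0.0961 and 0.138), but passed without Quad replicate 1 (0.30) and, in QuadD, without Ctrl-D replicate 1 (0.35). The eye colour gene w, a common marker of fly transgenes, rose by 0.70 ± 0.14 in Quad (adjusted p = 0.00808), a call lost without Ctrl replicate 2 (0.67). In QuadD it rose by 1.87 ± 0.11 (adjusted p = 0.000111).

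**Figure D1:**
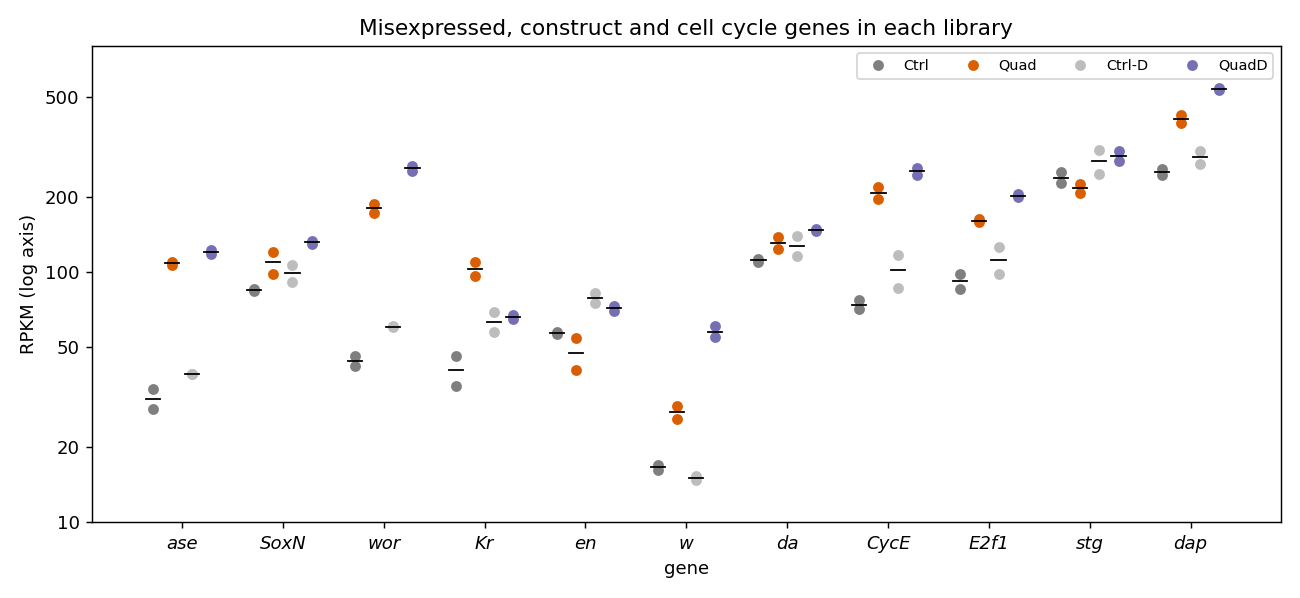
RPKM (log axis) of the 4 misexpressed genes, of en, w and da, and of the 4 cell cycle genes CycE, E2f1, stg and dap; each point is a library and each short bar the mean of the 2 libraries of a group. Both misexpression groups lie above their controls for ase and wor, whereas Kr does so in Quad, at 102.8 against 40.6 RPKM, and not in QuadD, at 66.1 against 63.3 RPKM.

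In Quad embryos, genes of the cell cycle rose together. CycE, the cyclin that starts S phase, rose from 74.0 ± 4.23 to 206.9 ± 15.4 RPKM (1.47 ± 0.10, adjusted p = 0.000251). E2f1, an activator of S phase genes, rose by 0.80 ± 0.10 (adjusted p = 0.00165), and the Cdk inhibitor dap rose by 0.70 ± 0.09 (adjusted p = 0.00181). The gene stg, the Cdc25 phosphatase that triggers mitosis, stood at 215.8 ± 12.04 RPKM against 237.9 ± 17.3 RPKM in Ctrl (adjusted p = 0.276). Of 37 DNA replication genes 36 rose and none fell (median log2 fold change 1.09, camera adjusted p = 1.73e-11). Among them were the origin recognition gene Orc1 (1.32 ± 0.10) and the helicase gene Mcm6 (1.22 ± 0.10). Of 32 mitosis genes 31 rose (median 1.13, adjusted p = 1.73e-11), including securin pim (1.56 ± 0.11) and the kinesin ncd (1.39 ± 0.11). Among cell cycle drivers 12 of 17 rose (median 1.00, adjusted p = 0.000339), and among cell cycle brakes 10 of 12 rose (median 0.64, adjusted p = 0.00316). Adjusted over the list alone, the counts of these 4 lists were the same. With an estimated correlation between genes no list in this comparison passed, and these 4 had an adjusted p = 0.525 with an estimated correlation. With fry, all 4 passed (largest adjusted p = 0.0357). Between the driver-only groups, Ctrl lay below Ctrl-D in the DNA replication list (median -0.41) and the mitosis list (-0.43).

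Several lists of neural genes had medians above 0 in Quad. Of all 10436 genes tested 2601 rose, a larger share than the 7 of 37 in the neuron differentiation list. Of 34 neuroblast and asymmetric division genes 21 rose and 2 fell (median 0.56, camera adjusted p = 0.000135; 21 and 2 adjusted over the list alone). They included mira, which anchors fate determinants in dividing neuroblasts and rose from 173.9 ± 1.55 to 551.8 ± 15.1 RPKM (1.66 ± 0.08, adjusted p = 9.5e-05). The Numb adaptor pon (1.35 ± 0.09) and the determinant pros (1.39 ± 0.11) rose as well, whereas Sox21b fell by 2.70 ± 0.19. In the temporal series, genes that neuroblasts express in sequence, 8 of 17 rose and 1 fell (median 0.43, adjusted p = 0.00802; 10 and 1 adjusted over the list alone). The early member hb rose by 1.47 ± 0.12 and the late member grh fell by 1.11 ± 0.10. RNA of whole embryos does not show whether these levels changed in neuroblasts or in other cells. Both lists had an adjusted p = 0.525 with an estimated correlation. Of 37 neuron differentiation genes 7 rose and 3 fell (median 0.51, adjusted p = 0.0227; 4 and 2 adjusted over the list alone), with an adjusted p = 0.788 with an estimated correlation and 0.398 with fry, so that its call was lost with either. Csp, a synaptic vesicle protein gene, rose by 0.96 ± 0.08, and the transcription factor gene Pdp1, which is also active in muscle, fell by 1.32 ± 0.18. Without Quad replicate 1 the neuron differentiation median was 0.092 and the call was lost; between the Quad libraries, replicate 2 minus replicate 1, the median difference of this list was -0.79.

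Genes of other tissues were mostly lower in Quad. Of 37 epidermis and cuticle genes 32 fell and 1 rose (median -1.84, camera adjusted p = 2.07e-12; 32 and 1 adjusted over the list alone). The chitin deacetylase gene verm went from 462.6 ± 98.5 to 20.8 ± 1.85 RPKM (-4.40 ± 0.16, adjusted p = 4.98e-05), and the zona pellucida domain gene neo fell by 3.49 ± 0.11. Of 18 trachea and salivary gland genes 17 fell (median -0.97, adjusted p = 1.77e-07), with PH4alphaSG2 at -3.41 ± 0.15. Of 24 gut and Malpighian tubule genes 17 fell and 3 rose (median -0.72, adjusted p = 0.00143), with bowl at -1.72 ± 0.13. Of 18 hemocyte and fat body genes 11 fell and 2 rose (median -0.90, adjusted p = 0.00344), with the prophenoloxidase gene PPO1 at -3.41 ± 0.14. Of 34 mesoderm and muscle genes 12 fell and 2 rose (median -0.57, adjusted p = 0.00802), with how at -0.78 ± 0.09. Adjusted over the list alone, the falls in these last 4 lists numbered 17, 17, 11 and 11, and the rises 0, 3, 2 and 2. All 5 lists had an adjusted p = 0.525 with an estimated correlation. The muscle call was also lost with fry (adjusted p = 0.159) and without Quad replicate 2, where the median was -0.18. Between the driver-only groups, Ctrl lay above Ctrl-D in the epidermis list (median 0.60) and the muscle list (0.35).

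Further lists moved in Quad. Of 26 maternal and germ line transcripts 12 rose and 1 fell (median 0.44, camera adjusted p = 0.00316; 12 and 1 adjusted over the list alone), with smg at 2.22 ± 0.20. Of 26 Polycomb and trithorax group genes 15 rose (median 0.48, adjusted p = 0.000277; 17 adjusted over the list alone), with Sfmbt at 1.06 ± 0.12. Both had an adjusted p = 0.525 with an estimated correlation. Of 24 heat shock and stress genes 9 fell and 1 rose (median -0.38, adjusted p = 0.0227; 9 and 0 adjusted over the list alone), with an adjusted p = 0.622 with an estimated correlation. Its members Hsf, the heat shock transcription factor gene, fell by 1.18 ± 0.09 and Hsc70-3 by 1.29 ± 0.10. Of 25 ribosome biogenesis and growth genes 8 fell (median -0.21, adjusted p = 0.0302; 5 adjusted over the list alone), with an adjusted p = 0.74 with an estimated correlation. Myc fell by 0.73 ± 0.15, a call lost without Ctrl replicate 1 (-0.61). The heat shock list lost its call with fry (adjusted p = 0.0811) and without Quad replicate 2 (median -0.40), and the ribosome biogenesis list with fry (adjusted p = 0.232), without Quad replicate 1 (-0.093) and without Ctrl replicate 1 (-0.18).

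**Figure D2:**
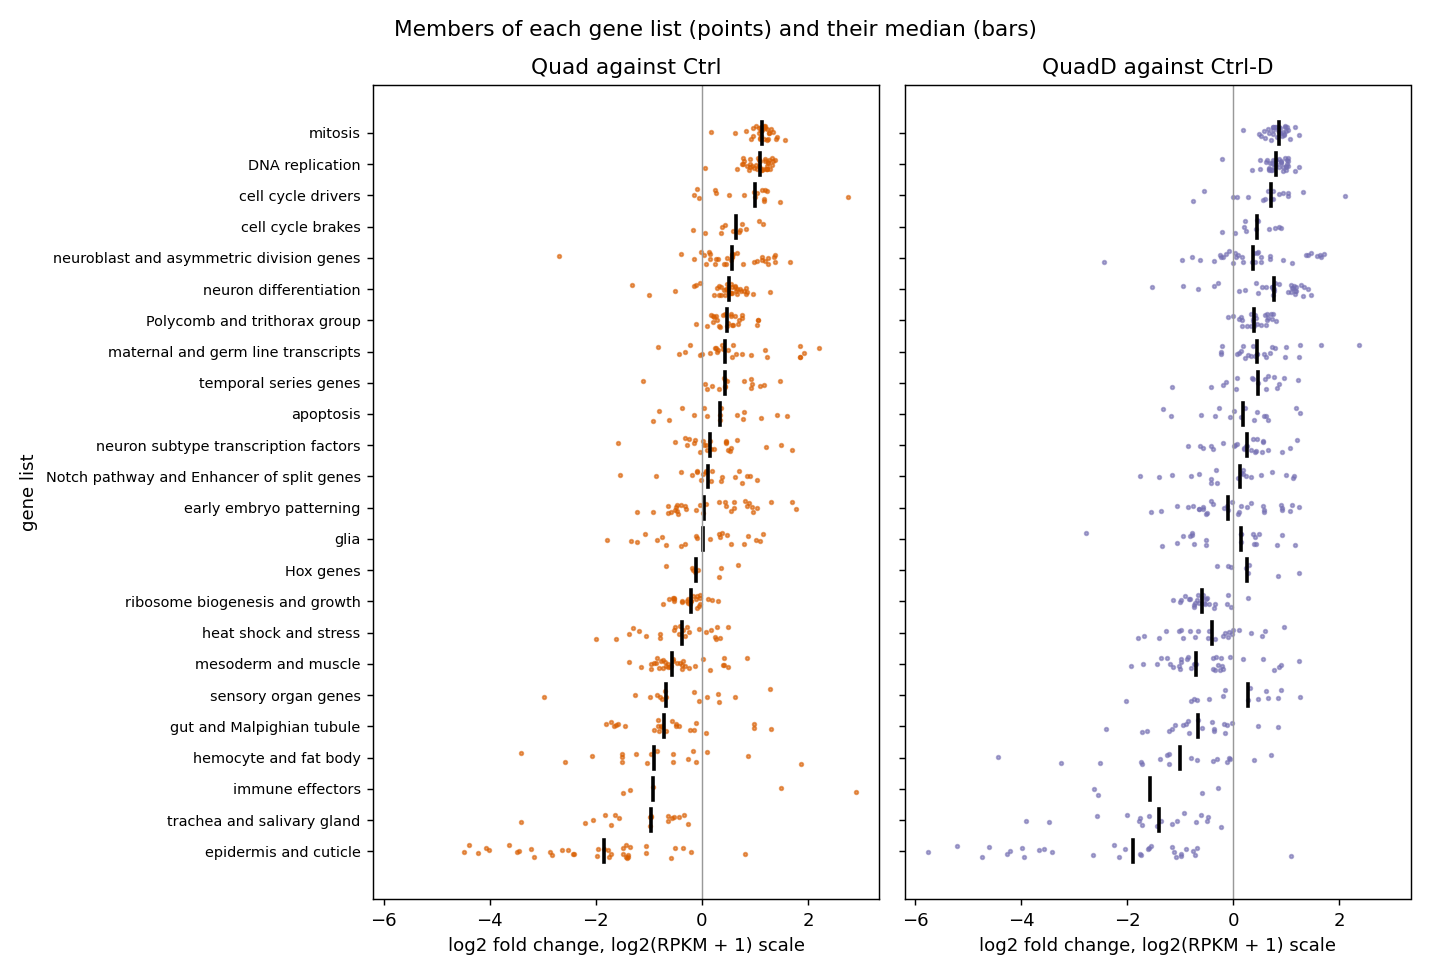
Log2 fold change of each tested member of the fixed gene lists (points) and the list median (black bars), in Quad against Ctrl and in QuadD against Ctrl-D, on the log2(RPKM + 1) scale. Mitosis and DNA replication genes lie mostly to the right of 0 in both panels, with medians of 1.13 and 1.09 in Quad, and epidermis and cuticle genes to the left, with medians of -1.84 in Quad and -1.90 in QuadD; the immune effectors had too few members for a list test in QuadD.

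Among single genes with at least 10 RPKM in the higher group and no overlap of the libraries, leaving out symbols that are only a CG or CR number, the largest rises in Quad included GstD7, a glutathione transferase gene, from 1.20 ± 0.309 to 138.6 ± 45.0 RPKM. Mabi rose from 3.35 ± 0.588 to 143.8 ± 9.02 RPKM, and lcs was listed at the floor of the table in Ctrl and at 39.6 ± 19.3 RPKM in Quad. Obp44a (3.78 ± 0.36), the neuroblast lineage factor eg (3.07 ± 0.18) and Cyp4p2 (2.98 ± 0.22) followed. The largest falls were in ImpE1 (-5.17 ± 0.25), spz6 (-5.07 ± 0.15), Spn100A (-5.05 ± 0.20), ImpL1 (-4.97 ± 0.23), Osi6 (-4.95 ± 0.34) and ect (-4.91 ± 0.22). ImpE1 and ImpL1 are known as ecdysone-inducible genes. Of 10436 genes tested 4956 passed, 2601 higher and 2355 lower; the balance turned with RLE scaling (2106 higher, 2657 lower) and widened with quantile normalization (2976 and 2302). Of those that passed, 1940 changed by at least 2-fold, 664 higher and 1276 lower. The count was 2714 without Ctrl replicate 1 and 2444 without Ctrl replicate 2.

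In QuadD embryos, cell cycle genes were higher as well. CycE rose from 101.6 ± 21.6 to 252.6 ± 12.04 RPKM (1.32 ± 0.15, adjusted p = 0.000978), E2f1 by 0.86 ± 0.12 (adjusted p = 0.00251) and dap by 0.90 ± 0.09 (adjusted p = 0.000731). The gene stg was at 290.6 ± 18.0 RPKM against 276.9 ± 42.9 RPKM (adjusted p = 0.618). Of 37 DNA replication genes 34 rose (median 0.81, camera adjusted p = 3.66e-08), among them the histone chaperone gene asf1 (1.01 ± 0.10). Of 32 mitosis genes 31 rose (median 0.85, adjusted p = 2.98e-08), among them the condensin gene glu (1.23 ± 0.13). Of 17 cell cycle drivers 12 rose and 2 fell (median 0.72, adjusted p = 0.00828), and of 12 cell cycle brakes 6 rose (median 0.44, adjusted p = 0.0194). Adjusted over the list alone, 35, 31, 13 and 6 members of these 4 lists rose and 1, 0, 2 and 0 fell. No list of this comparison passed with an estimated correlation, and each of these had an adjusted p = 0.663 with an estimated correlation. Between the controls, Ctrl-D lay above Ctrl in the DNA replication and mitosis lists (medians of Ctrl minus Ctrl-D -0.41 and -0.43). With fry all 4 lost their call as well (adjusted p = 0.0717 for DNA replication and for mitosis, 0.111 for drivers and 0.105 for brakes). The brakes call was also lost without Ctrl-D replicate 2 (median 0.27).

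Neural genes also rose in QuadD. Of 35 neuron differentiation genes 27 rose and 4 fell (median 0.77, camera adjusted p = 7.8e-06; 27 and 4 adjusted over the list alone; adjusted p = 0.663 with an estimated correlation). Among them, elav, a marker of all neurons, rose from 115.3 ± 5.17 to 249.0 ± 12.3 RPKM (1.10 ± 0.08), stai by 1.27 ± 0.10 and the synaptobrevin gene nSyb by 1.46 ± 0.12. Of 34 neuroblast and asymmetric division genes 17 rose and 4 fell (median 0.37, adjusted p = 0.0237; 17 and 4 adjusted over the list alone), with insc (1.71 ± 0.09), scrt (1.57 ± 0.08) and nerfin-1 (1.37 ± 0.08) among the rises. Of 17 temporal series genes 10 rose and 2 fell (median 0.46, adjusted p = 0.0445; 10 and 2 adjusted over the list alone), grh falling by a log2 fold change of -1.16 ± 0.09 and cas rising by 0.95 ± 0.10. Both lists had an adjusted p = 0.663 with an estimated correlation. Both lost their call without Ctrl-D replicate 2 (medians 0.39 and 0.31), and the temporal list also without QuadD replicate 1 (0.51). Of 26 Polycomb and trithorax group genes 19 rose (median 0.40, adjusted p = 0.00024), with ph-p at 0.59 ± 0.08. Of 25 maternal and germ line transcripts 11 rose (median 0.44, adjusted p = 0.00572), with stau at 0.70 ± 0.09. Both had the same counts adjusted over the list alone and an adjusted p = 0.663 with an estimated correlation; the maternal call was lost without Ctrl-D replicate 2 (median 0.48). With fry, the neuroblast, temporal and Polycomb calls (adjusted p = 0.0717 each) and the maternal call (0.114) were lost, and neuron differentiation passed (0.0272). Between the controls, Ctrl-D lay below Ctrl in the neuron differentiation list, by a median of 0.43.

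Several tissue groups were lower in QuadD. Of 30 epidermis and cuticle genes 29 fell and 1 rose (median -1.90, camera adjusted p = 5.5e-11). Gasp, a chitin-binding protein gene, went from 172.6 ± 16.3 to 8.36 ± 0.978 RPKM (-4.21 ± 0.12, adjusted p = 3.65e-05). Of 18 trachea and salivary gland genes 17 fell (median -1.40, adjusted p = 5.47e-07), including CrebA, a regulator of the secretory pathway, which fell by 1.77 ± 0.09. Of 25 ribosome biogenesis and growth genes 21 fell and 1 rose (median -0.59, adjusted p = 2.76e-05), and the snoRNP gene NHP2 fell by 0.99 ± 0.08. Of 18 hemocyte and fat body genes 12 fell and 2 rose (median -1.01, adjusted p = 0.000865), with PPO2 at -2.52 ± 0.12. Of 21 gut genes 15 fell and 1 rose (median -0.66, adjusted p = 0.00171), with bowl at -2.40 ± 0.18. Of 33 muscle genes 19 fell and 5 rose (median -0.71, adjusted p = 0.00171), with sns at -1.36 ± 0.13 and the myogenic factor nau at 1.24 ± 0.12. Adjusted over the list alone, 29, 17, 21, 12, 15 and 22 members fell and 1, 0, 1, 2, 2 and 5 rose. Each of these 6 lists had an adjusted p = 0.663 with an estimated correlation. Between the controls, Ctrl-D lay below Ctrl in the epidermis list, by a median of 0.60.

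Among single genes chosen in the same way, the largest rises in QuadD were in Cyp4p2 (3.40 ± 0.24), nvy (24.7 ± 1.85 to 190.7 ± 30.5 RPKM, 2.89 ± 0.13), Gr2a (2.66 ± 0.18), nrm (2.62 ± 0.13), Nep4 (2.38 ± 0.17) and pgc (2.37 ± 0.21). The largest falls were in Osi6 (-7.43 ± 0.18), ect (-6.78 ± 0.15), Osi7 (-6.26 ± 0.27), spz6 (-5.83 ± 0.16), verm (-5.76 ± 0.22) and ImpL1 (-5.55 ± 0.16). Of 10207 genes tested 5618 passed, 2794 higher and 2824 lower. This even split depended on the scaling, with 2424 higher and 3081 lower with RLE scaling and 3384 and 2452 with quantile normalization. It also shifted without QuadD replicate 1 (1615 and 2126), QuadD replicate 2 (1259 and 2034), Ctrl-D replicate 1 (2778 and 2350) or Ctrl-D replicate 2 (2256 and 1926). Of those that passed, 1887 changed by at least 2-fold, 537 higher and 1350 lower. The count was 3741 without QuadD replicate 1 and 3293 without QuadD replicate 2.

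Other lists had no call with camera, and their members moved both ways. With fry, sensory organ genes (lower, adjusted p = 0.0428), apoptosis genes (higher, 0.0418) and immune effectors (lower, 0.0302) passed in Quad, and Hox genes (higher, 0.0436) in QuadD. Glia genes had 8 rises and 9 falls among 22 in Quad (camera adjusted p = 0.842) and 7 rises and 10 falls among 21 in QuadD (adjusted p = 0.68). Gs2, a glutamine synthetase gene, fell by 1.06 ± 0.12 and 2.78 ± 0.09, whereas repo, a transcription factor of most glia, rose by 1.16 ± 0.10 in QuadD. Notch pathway and Enhancer of split genes had 7 rises and 3 falls among 20 in Quad and 5 rises and 7 falls in QuadD (adjusted p = 0.446 and 0.901), and the ligand gene Ser fell by 1.54 ± 0.15 and 1.77 ± 0.18. Early embryo patterning genes had 11 rises and 9 falls among 32 in Quad (adjusted p = 0.583) and 10 rises and 12 falls among 31 in QuadD (adjusted p = 0.751), with sna rising by 1.05 ± 0.09 and 1.11 ± 0.10. Neuron subtype factors had 6 rises and 2 falls among 25 in Quad and 11 and 4 in QuadD (adjusted p = 0.295 and 0.08), with ftz at 1.70 ± 0.18 and 1.07 ± 0.13. Sensory organ genes had 1 rise and 7 falls among 15 in Quad and 4 and 2 in QuadD (adjusted p = 0.146 and 0.676), with nompA at -2.97 ± 0.24 and -2.02 ± 0.17. Apoptosis genes had 7 rises and 3 falls among 16 in each (adjusted p = 0.254 and 0.355), with the cell death gene skl at 1.42 ± 0.14 and 1.18 ± 0.09. Hox genes had 2 rises and 1 fall among 8 in each (adjusted p = 0.961 and 0.205), with Antp at 0.68 ± 0.12 and 1.25 ± 0.09. Of 5 immune effectors tested in Quad 2 rose and 3 fell (adjusted p = 0.583). Heat shock genes in QuadD had 2 rises and 10 falls among 24 (adjusted p = 0.0685), and this list passed without QuadD replicate 1 (median -0.59) and without Ctrl-D replicate 1 (-0.57).

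Adjusted over the list alone, the rises and falls of these lists differed little. In Quad they were 8 and 9 for glia, 7 and 3 for Notch, 12 and 11 for early patterning, 5 and 2 for neuron subtype, 2 and 7 for sensory organ, 7 and 3 for apoptosis, 2 and 1 for Hox, and 2 and 3 for immune genes. In QuadD they were 8 and 10 for glia, 5 and 7 for Notch, 10 and 12 for early patterning, 11 and 4 for neuron subtype, 4 and 2 for sensory organ, 8 and 4 for apoptosis, 2 and 0 for Hox, and 2 and 10 for heat shock genes. Median and mean differed in sign for Hox genes in Quad (-0.11 and 0.014), for immune effectors in Quad (-0.93 and 0.12), for Notch genes in QuadD (0.12 and -0.080), and for glia genes in Quad (0.030 and -0.066) and in QuadD (0.14 and -0.23).

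The effects of Quad and QuadD were then set side by side, with no library serving both comparisons. Across the 9972 genes tested in both, the log2 fold changes had a Spearman correlation of 0.835; genes are not independent replicates, and no p-value is attached. Of these genes, 1881 were called higher in both comparisons, where independent lists of the same sizes would share 687.7. Another 1890 were called lower in both, against 619.6. Calls in opposite directions were made for 31 genes higher in Quad and lower in QuadD, against 704.3, and for 19 genes the other way round, against 605.0.

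**Figure D3:**
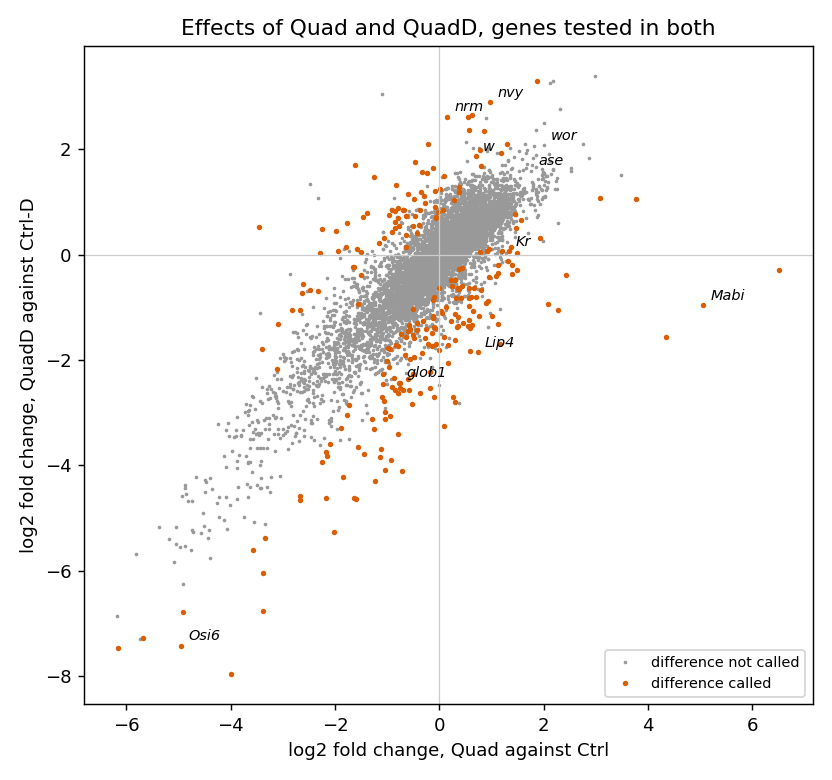
Log2 fold change in QuadD against Ctrl-D (y axis) plotted over that in Quad against Ctrl (x axis) for the 9972 genes tested in both; each point is a gene, and orange points are genes whose difference of effects passed the test. Most points run along the diagonal (Spearman correlation 0.835), with Mabi far to the right and nvy and nrm above.

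The test of the difference itself, (Quad - Ctrl) - (QuadD - Ctrl-D), asked where the effects in Quad and in QuadD parted. Besides the form of the factors named in the labels, these groups differed in Kr RNA, which was raised over its own control in Quad and not in QuadD. Kr differed by 1.26 ± 0.20 (adjusted p = 0.0138) and w by -1.17 ± 0.16 (adjusted p = 0.00679). The controls differed in Kr as well, with 40.6 RPKM in Ctrl and 63.3 RPKM in Ctrl-D, so the Kr difference includes that of the control levels. The genes ase (0.17 ± 0.14), wor (-0.077 ± 0.12), CycE (0.15 ± 0.19) and E2f1 (-0.056 ± 0.17) did not pass. The Kr call was lost without Ctrl replicate 2 (1.07), QuadD replicate 1 (1.23), QuadD replicate 2 (1.29) or Ctrl-D replicate 1 (1.13), and with no filter on low values (1.26). Leaving out symbols that are only a CG or CR number, the smallest p-values with the higher effect in Quad belonged to GstD7 (6.65 ± 0.37), Mabi (6.02 ± 0.34), Lip4 (2.59 ± 0.17), the globin gene glob1 (1.66 ± 0.13) and lcs. Of these, glob1 fell by 0.77 in Quad and by 2.43 in QuadD. With the higher effect in QuadD, and the same symbols left out, the smallest p-values belonged to Nplp3, nvy (-1.92 ± 0.18), nrm (-2.47 ± 0.24), dar1 (-2.05 ± 0.22) and Lcp65Ag1 (-2.94 ± 0.32). Of these, dar1 fell in both experiments, from 15.5 to 1.70 RPKM in Quad and from 12.9 to 8.43 RPKM in QuadD. Lcp65Ag1 was at 8.39 RPKM in Ctrl and 0.699 RPKM in Quad but at 0.145 RPKM in Ctrl-D and 0.598 RPKM in QuadD, and so had no level to fall from in the second experiment. Nplp3 was listed at the floor in both Ctrl-D libraries and at 9.56 and 10.1 RPKM in QuadD. In all, 291 of 10775 genes passed, 190 with the higher effect in Quad and 101 with the higher effect in QuadD. This count was 495 without Quad replicate 1 (245 and 250, with no excess on the Quad side), 141 without Ctrl replicate 1, 126 without Ctrl replicate 2, 183 without QuadD replicate 1 and 145 without QuadD replicate 2. It was 192 without Ctrl-D replicate 1, 188 without Ctrl-D replicate 2, 162 with no filter on low values and 174 with the replicate number as a block.

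Among the lists, the effects in Quad were higher than in QuadD for ribosome biogenesis genes (median difference 0.36, camera adjusted p = 0.000295), mitosis genes (0.31, adjusted p = 0.00366), immune effectors (1.17, adjusted p = 0.00895) and DNA replication genes (0.24, adjusted p = 0.0231). They were lower for sensory organ genes (-0.55, adjusted p = 0.000317) and neuron differentiation genes (-0.26, adjusted p = 0.00895). Between the controls, Ctrl minus Ctrl-D, these lists stood apart the opposite way, with medians of -0.21 for ribosome biogenesis, -0.43 for mitosis, -0.18 for immune effectors, -0.41 for DNA replication, 0.16 for sensory organ and 0.43 for neuron differentiation genes, so the differences of effects include those of the control levels. For mitosis, DNA replication and neuron differentiation genes, this gap between the controls was larger than the difference of effects itself. With an estimated correlation the adjusted p was 0.35 for the sensory organ list, 0.607 for the immune effectors and 0.867 for the other 4. Single members passed for 1 of 32 mitosis genes, 2 of 6 immune effectors and 3 of 16 sensory organ genes. None passed among 25 ribosome biogenesis, 37 DNA replication and 37 neuron differentiation genes. Adjusted over the list alone, 6 ribosome biogenesis, 1 mitosis and 3 immune genes were higher, and 5 sensory organ genes were lower and 1 higher. The DNA replication call was lost without Quad replicate 2 (0.095), Ctrl replicate 2 (0.22), QuadD replicate 1 (0.20) or Ctrl-D replicate 1 (0.057), and the mitosis call without Quad replicate 2 (0.19) or Ctrl-D replicate 1 (0.13). The immune call was lost without Quad replicate 1 (1.24) or Quad replicate 2 (1.04) and the neuron differentiation call without Ctrl-D replicate 1 (-0.17), while without Quad replicate 2 that list turned to 0.13. The lists that passed numbered 6 with every library, 2 without Quad replicate 2 and 3 without Ctrl-D replicate 1.

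With fry, a rotation test of the lists, the sensory organ list kept its call (adjusted p = 0.0335), Hox genes also passed (lower in Quad, adjusted p = 0.0335), and the other 5 lists lost theirs (0.592 for DNA replication, 0.471 for mitosis, 0.811 for neuron differentiation, 0.0974 for immune effectors and 0.198 for ribosome biogenesis). Some lists passed with camera after a library was left out but not with every library. These were early patterning genes without Quad replicate 1 (median 0.24), trachea and salivary gland genes without QuadD replicate 1 (0.21) and cell cycle drivers without Ctrl-D replicate 2 (0.50). Epidermis genes passed without Ctrl replicate 1 (-0.16) and without QuadD replicate 2 (-0.20), and Hox genes (-0.12) and heat shock genes (-0.25) also without QuadD replicate 2. With every library, muscle genes and maternal transcripts had medians above 0 (0.12 and 0.089) while camera pointed down (adjusted p = 0.461 and 0.531). Median and mean differed in sign for Notch genes (-0.013 and 0.23) and for neuron subtype factors (-0.091 and 0.004).

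The controls of both experiments had the same genotype, and their comparison measures what the experiment and its sequencing lane alone changed. It sets levels from separate tables side by side, whose RPKM were scaled per library. Epidermis and cuticle genes were higher in Ctrl than in Ctrl-D (median 0.60, camera adjusted p = 4.84e-12; 6 of 37 members passed, and 25 were higher and 1 lower adjusted over the list alone). Neuron differentiation genes (0.43, adjusted p = 7.48e-05), muscle genes (0.35, adjusted p = 0.00163) and heat shock genes (0.14, adjusted p = 0.0144) were also higher in Ctrl, with 0, 1 and 2 members passing. DNA replication genes (-0.41, adjusted p = 1.91e-10; 24 lower adjusted over the list alone) and mitosis genes (-0.43, adjusted p = 1.05e-09; 21 lower adjusted over the list alone) were lower in Ctrl, with no single member passing over all genes. Also lower were the lists of Notch genes (-0.38, adjusted p = 7.48e-05), early patterning genes (-0.23, adjusted p = 0.000571), neuroblast genes (-0.17, adjusted p = 0.00116), cell cycle drivers (-0.28, adjusted p = 0.00192), ribosome biogenesis genes (-0.21, adjusted p = 0.00941), cell cycle brakes (-0.20, adjusted p = 0.0102) and Polycomb and trithorax genes (-0.15, adjusted p = 0.027). Each of these 13 lists lost its call, with an adjusted p = 0.569 or 0.576 with an estimated correlation and at least 0.144 with fry. Of 10775 genes 133 passed, 81 higher in Ctrl and 52 higher in Ctrl-D. The count was 958 without Quad replicate 1 (472 and 486), 983 without Quad replicate 2 (494 and 489), 128 without Ctrl replicate 1 (119 and 9), 4 without Ctrl replicate 2, 66 without QuadD replicate 1 and 64 without QuadD replicate 2. It was 8 without Ctrl-D replicate 1, 5 without Ctrl-D replicate 2, 122 with the replicate number as a block (94 and 28) and 55 with no filter on low values.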

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

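The tests of explanations in this part were all chosen after the results were seen, whereas the test of the difference of effects was planned. By that test, the effects of Quad and QuadD differed for 190 genes with the higher effect in Quad and 101 with the higher effect in QuadD; without Quad replicate 1 these numbers were 245 and 250. Among the genes named by rule, the log2 difference, Quad minus QuadD, was 1.26 for Kr, -1.17 for w, 6.65 for GstD7, 6.02 for Mabi, 2.59 for Lip4, 1.66 for glob1, 5.25 for lcs, -3.43 for Nplp3, -1.92 for nvy, -2.47 for nrm, -2.05 for dar1 and -2.94 for Lcp65Ag1. The fitted values of lcs and Nplp3, listed at the floor in their controls, depend on the pseudocount and are no folds. Lcp65Ag1 was at 8.39 RPKM in Ctrl and 0.145 RPKM in Ctrl-D, and so had no level to fall from in the second experiment. Kr was at 40.6 RPKM in Ctrl and 63.3 RPKM in Ctrl-D, so its difference includes that of the control levels. Kr lost its call without Ctrl replicate 2 (1.07), QuadD replicate 1 (1.23), QuadD replicate 2 (1.29) or Ctrl-D replicate 1 (1.13). Among the lists, the median difference was 0.24 for DNA replication, 0.31 for mitosis, -0.26 for neuron differentiation, -0.55 for sensory organ genes, 1.17 for immune effectors and 0.36 for ribosome biogenesis. For DNA replication, mitosis and neuron differentiation, the controls stood apart the opposite way by more (Ctrl minus Ctrl-D, -0.41, -0.43 and 0.43). None of these lists passed with an estimated correlation (smallest adjusted p = 0.35, for sensory organ genes). Without Quad replicate 2 the neuron differentiation list turned to 0.13.

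GstD7, Mabi and lcs were high in Quad and not in the other groups, and Nplp3 in QuadD and not in the others. For such genes, a variant of the stock carried with the transgenes cannot be told apart from an effect of the factors, because 0 control libraries carried chromosomes of the transgenic stocks. An effect of the misexpressed factors stays open as well. The same limit applies to the other genes of both comparisons.

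Kr was not raised over Ctrl-D in the libraries labelled QuadD while wor was. Both QuadD libraries (64.8 and 67.4 RPKM) lay above both Ctrl libraries (46.1 and 35.2 RPKM), though Ctrl belongs to the other experiment. A Kr level that was high in Ctrl-D (69.2 and 57.5 RPKM) therefore stays open. Control libraries under a QuadD label are argued against, since the lowest QuadD value was 3.02 times the highest Ctrl-D value for ase and 3.59 times for w, genes outside this pattern. If the rise of wor were mostly RNA of the wor-EnR fusion with its en part counted under en, en would have risen, yet the upper end of its 95% interval was 0.082 on the log2 scale, against a rise of 2.08 for wor. This argues against that reading only if the embryo's own en RNA did not fall, which gene totals cannot show. A fusion whose en part is not counted under en stays open as well. A fall of the embryo's own Kr RNA offset by transgene RNA, with a sum of 0.066, may also underlie the Kr level and cannot be told apart here, because gene totals do not separate the sources.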

How the results depend on the processing

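Quantile normalization, the pseudocount of 0.1 and voom on genes with whole counts were chosen after the data were seen. The planned DESeq2 and edgeR fits were not run, since the files hold no whole counts for many genes. No gene called with the main settings changed sign under another scaling or pseudocount, or without any 1 library. The filters, the replicate block and the fit of all 8 libraries leave the log2 fold change of a gene as it is. They therefore could not turn a sign. Against 4956 genes in Quad and 5618 in QuadD, RLE scaling gave 4763 and 5505, quantile normalization 5278 and 5836, and the pseudocount of 0.1 gave 4892 and 5534. On genes with whole counts, voom called 2077 in Quad (1935 by the RPKM test, 1879 by both) and 2243 in QuadD (2169 and 2059), with 0 of opposite sign. These genes were chosen for counts proportional to RPKM, so the agreement in sign was built in. Quantile normalization moved the median of all genes by 0.10 in QuadD. Requiring at least 2-fold left 1940 genes in Quad and 1887 in QuadD, by construction. With no filter, the difference of effects fell from 291 to 162 genes and Ctrl against Ctrl-D from 133 to 55; the cause was not tested. Camera with an estimated correlation called 0 lists in Quad, 0 in QuadD and 0 for the difference of effects. At an unadjusted p under 0.05 it called 0, 0 and 1. The preset correlation called 16, 15 and 6, and fry 15, 8 and 2. Between Ctrl and Ctrl-D, which share a genotype, the preset correlation called 13 lists and fry 0. Small p-values with the preset correlation therefore do not separate an effect of the factors from differences between collections. With 2 libraries per group, the test with an estimated correlation has few degrees of freedom and little power. Calls lost with it therefore say little about a list. Why fry called fewer lists than the preset correlation was not tested.

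The correlation of same-numbered deviations was -0.043 in the first experiment and -0.095 in the second, which shows no pairing by replicate number. With 2 libraries per group, it cannot exclude that same-numbered libraries were collected or prepared together. With the replicate block the counts were 4729 genes in Quad, 5339 in QuadD, 122 for Ctrl against Ctrl-D and 174 for the difference of effects; the cause of the last was not tested.

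Leaving out each library in turn leaves a group with 1 library, which is then assumed to vary like the other groups. The counts ranged from 2444 to 5325 genes for Quad, 3293 to 5128 for QuadD, 126 to 495 for the difference of effects and 4 to 983 for Ctrl against Ctrl-D. Lists numbered 14 to 16 in Quad, 11 to 16 in QuadD and 2 to 9 for the difference. A Quad or QuadD library can move the comparison of controls only through the pooled spread and the filter. The correlation of both effects lay between 0.783 and 0.833, and was 0.873 for genes with a mean of at least 10 RPKM.

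Directions turned for some values near 0 and for list tests in some of the same leave-one-out fits. For a list the direction is that of the test, which can turn while the median keeps its sign. In QuadD, Kr ranged from -0.066 to 0.198 and stg from -0.081 to 0.235. In the difference of effects, SoxN ranged from -0.207 to 0.093, en from -0.342 to 0.076, da from -0.124 to 0.148, CycE from -0.068 to 0.366 and E2f1 from -0.230 to 0.117; da also turned to -0.032 with RLE scaling and -0.074 with quantile normalization. List medians in Quad ranged from -0.173 to -0.031 for Hox genes (test direction turned to up in some fits and with fry, where the median stays -0.109), -0.152 to 0.081 for glia and -0.018 to 0.356 for early patterning, and in QuadD from 0.028 to 0.138 for Notch genes, where the test direction alone turned. For the difference they ranged from -0.622 to 0.131 for neuron differentiation, -0.099 to 0.338 for muscle, -0.305 to 0.145 for epidermis, -0.043 to 0.147 for Polycomb and trithorax genes, -0.118 to 0.292 for maternal transcripts, 0.079 to 0.344 for cell cycle brakes (test direction alone), -0.065 to 0.180 for neuroblast genes, -0.071 to 0.107 for Notch genes and -0.269 to 0.158 for heat shock genes; with fry the test direction of the neuron subtype factors turned to up, the median staying -0.091. The cause was not tested. Depth of 39.6% to 42.5% of the deepest library limits genes with low levels in QuadD replicate 2 and both Ctrl-D libraries.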

Other observations

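The gene families, read from gene symbols, the comparison of opposite calls without each library and the tests of explanations were chosen after the data were seen; the gene lists, their tests and the test of the difference of effects were planned. Histone genes were higher in Quad for 112 of 117 genes tested (median log2 fold change 1.33) and in QuadD for 85 of 117 (1.02), with 0 lower; their copies are near-identical, so their reads are not unique to a copy. Nucleoporin genes rose in Quad for 19 of 19 and in QuadD for 18 of 19 (medians 0.73 and 0.50), and proteasome subunit genes for 24 and 17 of 34 (medians 0.42 and 0.28). Osiris genes fell for 15 of 15 tested in Quad (median -3.29) and 12 of 12 in QuadD (median -4.12). Coat and Sec genes of the secretory pathway fell for 18 of 26 in each (medians -0.49 and -0.55). Cytoplasmic ribosomal protein genes fell for 3 of 85 in Quad and 6 of 86 in QuadD, with 0 higher. All these medians kept their sign with RLE scaling and with quantile normalization. No member of the histone, nucleoporin, proteasome, secretory or ribosomal protein family passed the test of the difference of effects.

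For 50 genes the calls in Quad and QuadD had opposite signs, and for 46 of them the difference itself passed. Only 7 of the 46 kept both calls without each library in turn. Among the 7, ems, a head and brain transcription factor gene, was at 0.67 in Quad and -0.63 in QuadD, Brd at 0.70 and -0.81, and Lip4 at 0.73 and -1.86. The transcription factor genes D (0.56 and -0.97), tup (-0.50 and 0.54) and sv (-0.80 and 0.89) lost the call in Quad without Ctrl replicate 1.

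Epidermis and cuticle genes were lower (medians -1.84 in Quad and -1.90 in QuadD) while DNA replication and mitosis genes were higher, and these lists also parted between the controls. With an estimated correlation, a test of little power here, these calls were all lost (adjusted p = 0.525 in Quad, 0.663 in QuadD and 0.569 between the controls). With fry, the epidermis call was kept in Quad (adjusted p = 0.0297) and in QuadD (0.0272). The DNA replication and mitosis calls were kept with fry in Quad (0.0357 and 0.0302) and lost in QuadD (0.0717 each). Between the controls, fry lost these calls (adjusted p of at least 0.144). Scaling of the libraries is argued against as the cause of this parting, since a scale factor moves all genes of a library the same way. The DNA replication medians were 1.09 in Quad and 0.81 in QuadD, opposite to the epidermis medians. RLE scaling and quantile normalization moved the median of all genes by at most 0.10 on the log2 scale. Both rest on most genes keeping their level, so this small shift does not test a change of total RNA. Younger embryos would lower neuron differentiation genes if that list follows age as the epidermis list would. Its median was 0.51 in Quad (0.092 without Quad replicate 1) and 0.77 in QuadD. In QuadD the lower end of its 95% bootstrap interval was at least 0.62 without each library in turn. That interval resamples list members, which are not independent replicates, and does not measure the spread between libraries. The medians of the neuron and epidermis lists had the same sign between the controls (0.43 and 0.60) and between the replicates, 2 minus 1, of Quad (-0.79 and -0.098), QuadD (-0.064 and -0.21) and Ctrl-D (0.091 and 0.23), but not of Ctrl (-0.030 and 0.33), and the neuron list's call between the controls was lost with an estimated correlation (adjusted p = 0.576) and with fry (0.286). The neuron list values in QuadD go against younger embryos as the whole cause only under that premise, which these few pairs leave unsettled. Maternal and germ line transcripts would be higher in younger embryos if they decline with age. In Quad 12 of 26 rose and 1 fell (median 0.44). In QuadD 11 of 25 rose and 0 fell (median 0.44), a list call lost with fry (adjusted p = 0.114). Age therefore cannot be told apart from an effect of the factors in either experiment. A larger share of nervous tissue may contribute and stays open, since glia genes moved both ways (median 0.030 in Quad, 95% bootstrap interval over members -0.57 to 0.47), as does an effect of the factors on the cell cycle, which the design names.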
